A study of Arabidopsis thaliana with 12 samples.

How the data were processed

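RNA was measured in whole Arabidopsis thaliana Col-0 seedlings in 12 libraries, 4 groups of 3. Per the labels' protocols, seeds were stratified for 3 days, grown for 5 days at 22 °C and 16 h light on plates with or without SA187, and moved, 6 to a plate, to fresh plates with 0 or 100 mM NaCl for 12 days. Libraries were made from 1 µg of total RNA and read in pairs of 101 bases, per the labels. Ribosomal RNA was removed from the control and salt libraries with a plant leaf solution, and from the SA187 and salt with SA187 libraries with that solution mixed with one for bacterial and animal samples, per the labels. The mix therefore goes with inoculation in every library.

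The authors deposited FPKM values, 1 per gene and library, for 27371 plant and 4120 bacterial genes in one table. Per the submitters' processing notes, Trimmomatic and TopHat and the build TAIR10 were used, without versions. The tool that made the FPKM values, its strand setting and its treatment of shared reads are not given in the sources used here. The deposited FPKM are not counts, so no count test was used. The values of some very short genes are extremely high, and a plastid gene took most of the total in each library, so sums of values were not used as depth.

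Relative depth was read from genes above 0 in at most 8 libraries. It came from the commonest ratio of their values to those in salt with SA187 replicate 1. Those ratios gave 0.624 to 1 of the deepest library, control replicate 1. In the 11 libraries compared with salt with SA187 replicate 1, 61.8% to 80.7% of the ratios lay within 0.02 (log2) of a power-of-2 step. In the other 5 inoculated libraries bacterial values gave steps within 0.01 of those of plant values. The total read counts stay unknown, so no counting intervals are given.

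Each library was divided by its median ratio to the gene-wise geometric mean over 21427 nuclear genes above 0 in all libraries, giving rescaled FPKM. The factors were 0.917 to 1.13. Genes with FPKM of at least 1 in at least 3 libraries were tested (16729, 202 of them organellar) as log2(rescaled FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend, two-sided, Benjamini-Hochberg adjustment over all tested genes, called at an adjusted p under 0.05). All 4 groups shared one estimate of the spread. The 4 comparisons were SA187 against control, salt against control, salt with SA187 against salt, and salt with SA187 against SA187, with the interaction of salt and SA187. Bacterial genes were rescaled and tested alone in the 6 inoculated libraries by the same rule.

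The gene lists, 25 in number, the tests, the rule for named genes and most alternatives were chosen before the data were examined. Lists with at least 5 tested genes (21) were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation, with which no list passed in any comparison. The auxin (3 tested genes), heat shock (4) and floral (1) lists were too small for it, and the loci of the ribosomal RNA list were not among the tested genes (0). The rule names, for each comparison of 2 groups, the 5 largest rises and the 5 largest falls among called genes with separate group ranges and a reference symbol, the 3 largest called members of a list with at least 3 called, the 1 largest of a list with fewer, and, as a value only, the 1 largest of a list with none. For the interaction only the first part applies. The names came from a reference table of assembly TAIR10.1, in which 26699 of 27371 plant identifiers had a match. Since its name differs from the build TAIR10 of the files, no coordinates are printed.

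Genes whose group ranges do not overlap made up 43.9% of tested genes for salt, 24.8% for SA187 under salt, 26.6% for salt with SA187 and 16.8% for SA187 without salt, where chance gives 10%. Same-numbered control and SA187 libraries deviated together from their group means (correlations of 0.13, 0.38 and 0.11, all over 0.1). The numbers were therefore taken to pair these libraries, and the pairing comes from the values, not from the labels. It is weak, since control replicate 1 correlated more with SA187 replicate 3 (0.16) than with SA187 replicate 1. Counts with and without the block had been seen before the limit of 0.1 was applied.

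The tests were checked on simulated data with 200 changed genes among 16729 and noise drawn separately for each gene. Such noise holds no deviation of a library that many genes share, so recovery and false calls in the real data may differ. For SA187 under salt, 73%, 91% and 97.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and for the interaction 37%, 79% and 97%. Alternatives covered the pseudocount (0.1, 0.5), the filter (none, or a mean of at least 5), the scaling (as deposited, quantile, equal nuclear sum), eBayes without trend, array weights, only the libraries compared, a replicate block and each library left out. A covariate made of the mean log2 level of the clock list (the clock score) was added after seeing the data. Tests by count models do not apply to FPKM and were not run. Figures were drawn with matplotlib 3.10.9. In the simulations with a random direction of the SA187 effect, fitted effects were multiplied by 0.923 (salt) and 0.797 (SA187) to take out noise variance, and 1030 SA187 calls were made on average.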

Results

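The series measured RNA of whole Arabidopsis thaliana seedlings (ecotype Col-0, wild type) grown with or without the bacterium Enterobacter sp. SA187, an endophyte that lives inside plant tissue, and with or without 100 mM NaCl. The series title names the question: how SA187 gives plants tolerance of abiotic stress, and the part of ethylene signalling in it. The 12 libraries fall into 4 groups of 3 biological replicates: control, SA187, salt, and salt with SA187. Seedlings were 17 days old at harvest, after 12 days on the salt or salt-free plates. The deposited values are FPKM (fragments mapped to a transcript, corrected for its length and for the depth of the library) for 27371 plant genes and 4120 genes of the bacterium. Levels below are rescaled FPKM as mean ± SD of the 3 libraries of a group (n = 3), and changes are differences of mean log2(rescaled FPKM + 1), which understate the change of low genes.

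Total read counts per library are not given in the values, but the steps between the lowest values give relative depth. By those steps the shallowest library (control replicate 3) had 0.624 of the depth of the deepest (control replicate 1). Between 15198 and 16460 plant genes reached an FPKM of 1 in a library. The inoculated libraries had 3629 to 3817 bacterial genes above 0, and the others 50 to 124. The first principal component held 46.9% of the variance and placed the salt libraries farthest from the control and SA187 libraries, with the salt with SA187 libraries between them.

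**Figure D1:**
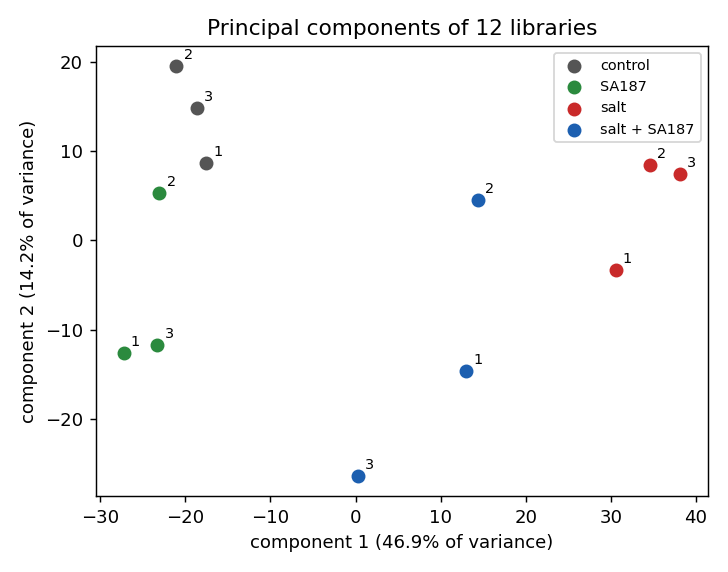
Scores of the 12 libraries on the first principal component (x axis, 46.9% of variance) and on the other plotted component (y axis, 14.2% of variance) of log2(rescaled FPKM + 1); each point is a library, coloured by group and numbered by replicate. The salt with SA187 libraries have first-component scores of 0.24 to 14.37, and the salt libraries 30.56 to 38.12.

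The salt comparison asks which plant genes respond to 100 mM NaCl in the absence of the bacterium. By camera with a preset correlation, salt raised the gene lists of the abscisic acid (ABA) and osmotic stress response, of flavonoid and anthocyanin synthesis and of jasmonate, and lowered those of salicylic acid defence and of photosynthesis. None of these lists passed with an estimated correlation (adjusted p = 0.43 to 0.89). P5CS1 (AT2G39800), which makes the proline precursor, rose from 3.22 ± 0.0883 to 23.9 ± 0.772, and KIN1 (AT5G15960), a cold and ABA induced gene, rose from 6.63 ± 3.14 to 81 ± 27.2. PCC1 (AT3G22231), a defence-associated gene, fell from 44.3 ± 18.7 to 0.978 ± 0.255. Of 16729 tested genes, 4430 passed an adjusted p of 0.05, 1851 higher and 2579 lower with salt, and 487 of them changed at least 2-fold.

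The 5 largest rises among genes with separate group ranges and a reference symbol were those of EARLI1 (AT4G12480), LTP2 (AT2G38530), MBP1 (AT1G52040), KIN1 and NAS2 (AT5G56080). EARLI1, which encodes a lipid transfer-like protein, rose from 2.22 ± 0.896 to 43.5 ± 2.1. LTP2, a lipid transfer protein gene, rose from 6.4 ± 2.1 to 95.3 ± 24.6. NAS2, a nicotianamine synthase gene of metal transport, rose from 3.94 ± 1.61 to 49.6 ± 11.8, and MBP1, a myrosinase-binding protein gene, reached 32.7 ± 9.27. AT5G64395, a locus without a symbol, was named after its values were seen. It was listed at 0 in the control libraries and had a larger fitted change (14.85, adjusted p = 0.0035). The number of fragments behind its values is not known and may be very small, so this change is not read as a large induction. By the same rule the 5 largest falls were those of PCC1, LURP1 (AT2G14560), ACD6 (AT4G14400), WRKY70 (AT3G56400) and PYL6 (AT2G40330). ACD6, an ankyrin protein gene of salicylic acid signalling, fell from 39.8 ± 13.4 to 2.52 ± 0.0779, and PYL6, an ABA receptor gene, fell from 4.99 ± 0.443 to 0.177 ± 0.0832. The log2 change of PCC1 was -4.44 (SE 0.37, adjusted p = 9.8e-06), and that of EARLI1 was 3.82 (SE 0.24, adjusted p = 1.6e-06).

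In the ABA and osmotic stress list, 18 of 32 measured genes rose and 0 fell (21 rose when adjusted over the list alone). The largest changes were KIN1, P5CS1 and HAI2 (AT1G07430), a protein phosphatase gene of ABA feedback, which rose from 0.436 ± 0.0981 to 4.17 ± 0.747. The list was higher by camera (adjusted p = 1.4e-11; adjusted p = 0.43 with an estimated correlation). In the flavonoid and anthocyanin list, 7 of 12 genes rose and 1 fell. DFR (AT5G42800), UGT79B1 (AT5G54060) and LDOX (AT4G22880), late enzymes of anthocyanin synthesis, rose to 40.2 ± 13.9, 39.7 ± 8.13 and 46.4 ± 12.2 from 6.31 ± 1.93, 7.16 ± 2.08 and 9.35 ± 3.22 (list adjusted p = 0.002; adjusted p = 0.8 with an estimated correlation). Of the jasmonate list, 5 of 19 genes rose, among them the storage protein gene VSP2 (AT5G24770), CORI3 (AT4G23600) and the lipoxygenase gene LOX2 (AT3G45140). VSP2 rose from 54.9 ± 13 to 143 ± 6.94 (list adjusted p = 0.0077; adjusted p = 0.89 with an estimated correlation). The list median was 0.27, and 0.09 without salt replicate 1. It was -0.01 with libraries scaled to equal nuclear sums, a scaling that lowered the median of all genes by 0.23.

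In the salicylic acid list, 7 of 12 genes fell and none rose (list adjusted p = 1e-05; adjusted p = 0.43 with an estimated correlation). The transcription factor genes WRKY70 and WRKY54 (AT2G40750) fell from 28 ± 14.1 and 5.78 ± 1.94 to 3.39 ± 0.845 and 0.73 ± 0.3, and NIMIN1 (AT1G02450), a partner of the salicylic acid receptor, fell from 6.47 ± 1.93 to 0.531 ± 0.119. In the immunity and camalexin list, 4 of 15 genes fell: FLS2 (AT5G46330), the flagellin receptor gene, went from 2.4 ± 0.229 to 0.473 ± 0.0726, and NHL10 (AT2G35980) and CYP71A12 (AT2G30750) had log2 changes of -1.78 and -1.39. That list did not pass camera (adjusted p = 0.14). In the photosynthesis list, 12 of 34 genes fell and 2 rose (list adjusted p = 0.0059; adjusted p = 0.89 with an estimated correlation). RBCS3B (AT5G38410), a Rubisco small subunit gene, fell from 3380 ± 361 to 1720 ± 196, while the light-harvesting genes LHCB2.2 (AT2G05070) and LHCB2.1 (AT2G05100) rose to 121 ± 46.5 and 133 ± 44.1. These genes belong to families of near-identical copies, so their values are uncertain where reads could be shared, and the list did not pass with quantile normalization (adjusted p = 0.31) or the clock score as covariate (adjusted p = 0.09).

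Of the ethylene response list, 4 of 16 genes fell, among them the defensin gene PDF1.2 (AT5G44420), listed at 0 in all 3 salt libraries, RAV1 (AT1G13260), from 8.73 ± 2.53 to 1.73 ± 0.521, and ORA59 (AT1G06160), from 2.31 ± 0.138 to 0.425 ± 0.21. The list did not pass camera (adjusted p = 0.1), but it was lower as deposited (median -0.31, adjusted p = 0.011), with the clock score (median -0.58, adjusted p = 0.02) and without control replicate 2 (median -0.80, adjusted p = 0.014). Of the ethylene biosynthesis list, 2 of 5 genes fell, the larger change being that of the oxidase gene ACO3 (AT1G12010), from 3 ± 0.337 to 0.595 ± 0.0473 (list adjusted p = 0.043; adjusted p = 0.43 with an estimated correlation). No member of the ethylene signalling list passed; the member with the largest change was EBF1 (AT2G25490), 23.7 ± 1.22 with salt against 18.7 ± 1.3. In the hypoxia list 3 of 5 genes rose, ADH1 (AT1G77120), SUS1 (AT5G20830) and LBD41 (AT3G02550), with ADH1, an alcohol dehydrogenase gene, going from 0.965 ± 0.163 to 2.96 ± 0.0946 (list adjusted p = 0.043; adjusted p = 0.48 with an estimated correlation). The ethylene biosynthesis list did not pass with quantile normalization (adjusted p = 0.052) or the replicate block (0.054), nor the hypoxia list with either (0.077 and 0.062), as deposited (0.08) or with the clock score (0.07). Without single libraries the ethylene biosynthesis list was lost for control replicate 1, salt replicate 2 and each salt with SA187 replicate (adjusted p = 0.052 to 0.057). The hypoxia list was lost for control replicate 3, SA187 replicate 1, salt replicates 1 and 2 and salt with SA187 replicates 1 and 3 (0.051 to 0.058), the photosynthesis list for control replicate 2 (0.059) and the jasmonate list for salt replicate 1 (0.07). Lists gained were immunity without control replicate 2 (lower, 0.046) and phosphate without salt replicate 3 (higher, 0.032).

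In the nitrogen list 3 of 9 genes rose and 4 fell. ASN1 (AT3G47340), an asparagine synthetase gene, and NRT2.1 (AT1G08090), a high-affinity nitrate transporter gene, rose to 9.16 ± 1.41 and 34.7 ± 11.6 from 1.04 ± 0.127 and 6.03 ± 1.06, and the nitrate reductase gene NIA1 (AT1G77760) fell from 69.6 ± 5.44 to 30.5 ± 1.09. The median of that list was -0.49 and its mean 0.14, so they differ in sign, and it did not pass camera (adjusted p = 0.74, direction down). In the ion transport list 3 of 12 genes rose and 3 fell: CAX1 (AT2G38170), a calcium exchanger gene, fell from 20.9 ± 5.18 to 9.77 ± 2.98, CAX3 (AT3G51860) rose to 2.6 ± 0.28, and AVP1 (AT1G15690), the vacuolar proton pump gene, fell to 115 ± 8.71. In the phosphate list 3 of 9 genes rose, among them the phosphate transporter genes PHT1;1 (AT5G43350) and PHT1;4 (AT2G38940) and PS2 (AT1G73010), and 1 fell. In the glucosinolate list 3 of 13 rose and 2 fell, with MYB29 (AT5G07690) and MAM1 (AT5G23010) higher and CYP79F2 (AT1G16400) lower, from 7.99 ± 0.163 to 2.72 ± 0.383. In the iron list 3 of 18 rose and 2 fell: the iron transporter gene IRT1 (AT4G19690) rose to 52 ± 5.87 from 20.8 ± 10.9, and F6'H1 (AT3G13610) and IRT2 (AT4G19680) fell. Single members passed in the oxidative stress list (FSD1 (AT4G25100), lower) and the clock list (ELF4 (AT2G40080), higher), but 0 passed in either when adjusted over the list alone, and these calls were lost in 14 and 7 alternatives. None passed in the sulfur, auxin, heat shock, senescence or cell division lists. The members with the largest change stood with salt at 24.3 ± 15 (LSU1 (AT3G49580)), 29.8 ± 2.86 (IAA2 (AT3G23030)), 1.8 ± 0.0609 (a small heat shock protein gene, AT5G59720), 1.23 ± 0.467 (NAC6 (AT5G39610)) and 5.1 ± 0.536 (CDKB1;1 (AT3G54180)).

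Adjusted over the list alone, genes that rose and fell numbered 7 and 2 (flavonoid), 5 and 0 (jasmonate), 0 and 10 (salicylic acid), 0 and 4 (immunity), 2 and 12 (photosynthesis), 0 and 5 (ethylene response) and 0 and 2 (ethylene biosynthesis). For further lists these were 3 and 0 (hypoxia), 3 and 5 (nitrogen), 3 and 4 (ion transport), 3 and 1 (phosphate), 3 and 2 (glucosinolate), 3 and 2 (iron) and 0 and 5 (root).

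In the root list 5 of 14 genes fell and none rose, the list did not pass camera (adjusted p = 0.21), and the Casparian strip genes CASP1 (AT2G36100) and CASP2 (AT3G11550) had log2 changes of -1.17 and -0.97. The floral regulator SOC1 (AT2G45660), the only measured member of its list, fell from 4.72 ± 0.923 to 2.54 ± 0.118. With the values as deposited, without rescaling, 5722 genes passed with 4046 higher and 1676 lower, and with equal nuclear sums 2169 passed with 248 higher and 1921 lower, so the direction split depends on the scaling. The count was 2729 without salt replicate 3 and 2846 without salt replicate 2. Other named calls were lost in 7 alternatives (AVP1 and LHCB2.1), 6 (IRT1) and 5 (LHCB2.2 and LBD41).

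The next comparison asks what SA187 changes in seedlings under salt. The ABA and osmotic stress list was lower with SA187 under salt (adjusted p = 3.8e-21; adjusted p = 0.26 with an estimated correlation), and the sodium transporter gene HKT1 (AT4G10310) was higher. RAB18 (AT5G66400), a dehydrin gene, fell from 43.8 ± 15.6 in salt to 4.77 ± 0.583 in salt with SA187, and RD29A (AT5G52310), a classical ABA and drought reporter gene, fell from 16.1 ± 4.23 to 4.01 ± 1.55. HKT1 rose from 0.546 ± 0.0629 to 1.59 ± 0.108. Of 16729 genes 770 passed, 466 higher and 304 lower, and 77 changed at least 2-fold. The count was 122 without salt replicate 3, 166 without salt replicate 2, 173 without salt with SA187 replicate 3, 411 without control replicate 3 and 1231 without salt with SA187 replicate 2.

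Of the ABA and osmotic stress list 19 of 32 genes fell and none rose (25 fell when adjusted over the list alone), with a median log2 change of -0.65. The largest were RAB18, at -2.90 (SE 0.67, adjusted p = 0.035), the late embryogenesis gene LEA7 (AT1G52690), from 4.98 ± 1.32 to 0.658 ± 0.185, and RD29A, at -1.79 (SE 0.31, adjusted p = 0.012). Among genes with separate ranges and a symbol, the 5 largest falls were those of RAB18, NAS2, LEA7, RD29A and MBP1; NAS2 fell from 49.6 ± 11.8 to 10.8 ± 3.43 and MBP1 to 9.63 ± 2.39. By the same rule the 5 largest rises were those of WRKY70, ERF2 (AT5G47220), ACHT5 (AT5G61440), BT5 (AT4G37610) and PCC1. WRKY70 rose from 3.39 ± 0.845 to 13.8 ± 6.55 and PCC1 from 0.978 ± 0.255 to 4.61 ± 1.39. ACHT5, a thioredoxin gene, rose from 4.3 ± 1.25 to 14.8 ± 5.85, and BT5 from 5.16 ± 2.45 to 17.2 ± 9.49.

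In the ethylene response list 1 of 16 genes rose, ERF2, from 0.909 ± 0.528 to 5.69 ± 4.12; 5 rose when adjusted over the list alone. The list was higher by camera (adjusted p = 0.0043; adjusted p = 0.66 with an estimated correlation), but not with a clock score as covariate (adjusted p = 0.25, median 0.16). Its score, the centred mean of the list, was 0.03, -0.52 and 0.44 in the salt with SA187 libraries and -0.31, -0.73 and -0.78 in the salt libraries, so salt with SA187 replicate 2 lay within the salt range. In the ethylene biosynthesis list ACO3 rose, from 0.595 ± 0.0473 to 1.53 ± 0.239 (list adjusted p = 0.036; adjusted p = 0.51 with an estimated correlation), and the list did not pass with the clock score (adjusted p = 0.16). In the salicylic acid list WRKY70 rose, and in the immunity list NHL10 rose to 1.55 ± 0.115 from 0.879 ± 0.0268. Both lists passed camera (adjusted p = 0.023 and 0.023; adjusted p = 0.66 and 0.62 with an estimated correlation), and neither passed with the clock score (adjusted p = 0.63 and 0.48). In the clock list 2 of 8 genes fell, the larger change being that of ELF4, from 13.4 ± 1.37 to 8.23 ± 1.84 (list adjusted p = 0.023; adjusted p = 0.66 with an estimated correlation). The clock list did not pass as deposited (adjusted p = 0.08). The clock score, the centred mean of this list, was -0.41, -0.09 and -0.41 in the salt with SA187 libraries and -0.14, 0.13 and 0.29 in the salt libraries.

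In the photosynthesis list 2 of 34 genes rose, the larger change being that of RBCS3B, from 1720 ± 196 to 3230 ± 786 (list adjusted p = 0.0049; adjusted p = 0.7 with an estimated correlation). In the flavonoid list PAP1 (AT1G56650), a MYB activator of anthocyanin genes, fell from 6.82 ± 1.28 to 3.6 ± 0.456, and 6 of 12 fell when adjusted over the list alone (list adjusted p = 0.00049; adjusted p = 0.62 with an estimated correlation). In the ion transport list HKT1 rose and CAX3 and the potassium channel gene GORK (AT5G37500) fell, CAX3 to 1.8 ± 0.0932 and GORK from 1.57 ± 0.185 to 1.15 ± 0.095. HKT1 had a log2 change of 0.74 (SE 0.06, adjusted p = 0.00011). ASN1 fell from 9.16 ± 1.41 to 3.13 ± 0.473, ADH1 from 2.96 ± 0.0946 to 1.3 ± 0.19, the senescence gene SAG29 (AT5G13170) from 1.06 ± 0.276 to 0.207 ± 0.0877, and the jasmonate-inactivating CYP94B3 (AT3G48520) from 4.37 ± 0.429 to 2.48 ± 0.191. The hypoxia list, with ADH1 its called member, passed camera (adjusted p = 0.049; adjusted p = 0.62 with an estimated correlation). SPX1 (AT5G20150) and the superoxide dismutase gene CSD2 (AT2G28190) rose, to 15.2 ± 0.749 and 8.36 ± 1.28, and the transporter gene ABCG37 (AT3G53480) fell to 4.74 ± 0.527. No member passed in the ethylene signalling, glucosinolate, sulfur, auxin, heat shock, root, floral or cell division lists. The members with the largest change stood in salt with SA187 at: EBF1 18.4 ± 2.92, MYB29 7.64 ± 0.693, GGCT2;1 (AT5G26220) 1.31 ± 0.442, IAA1 (AT4G14560) 10.4 ± 2.52, HSP70 (AT3G12580) 12.4 ± 2.32, ESB1 (AT2G28670) 2.06 ± 1.04, SOC1 2.88 ± 0.254 and CDKB1;1 4.36 ± 0.917. The hypoxia list did not pass as deposited (adjusted p = 0.098), with quantile normalization (0.087), with the replicate block (0.058) or with the clock score (0.066), nor the photosynthesis list with quantile normalization (0.61). Without salt replicate 2 the ethylene biosynthesis (0.065) and immunity (0.07) lists were lost, and without salt with SA187 replicate 1 these 2 (0.092 and 0.06), the salicylic acid list (0.073) and the clock list (0.073). The hypoxia list was lost without control replicates 2 or 3, salt replicates 1 or 2 or salt with SA187 replicate 2 (0.051 to 0.21). Lists gained were glucosinolate (lower with quantile normalization, 0.009, and without salt replicates 2 or 3, 0.016 and 0.0032), jasmonate (higher) and iron (lower) without salt with SA187 replicate 2 (both 0.023), and ion transport and senescence (both lower) without salt with SA187 replicate 3 (0.043 and 0.035).

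**Figure D2:**
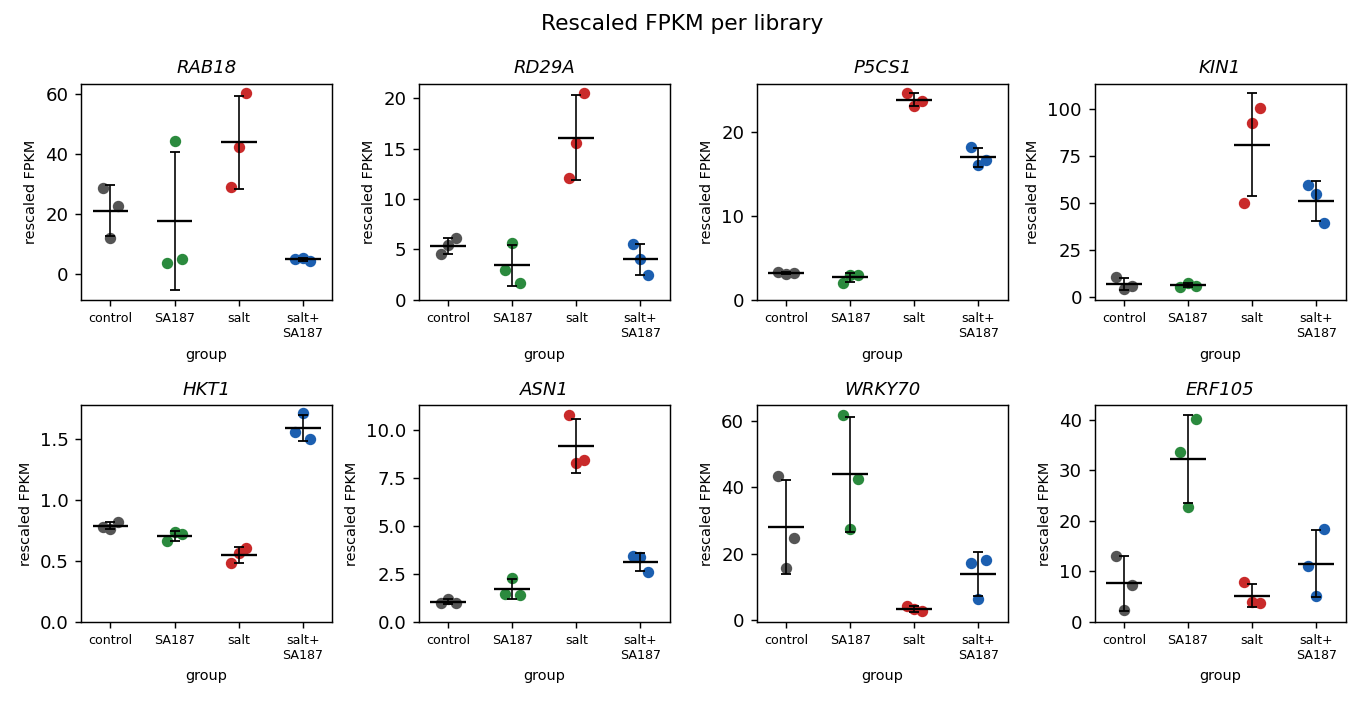
Rescaled FPKM (y axes) of 8 genes in the 4 groups (x axes); points are libraries, horizontal lines group means and error bars the SD of 3 libraries. RAB18 lies at 29 to 60.1 in salt and at 4.14 to 5.3 in salt with SA187, and SA187 replicate 2 stands at 44.3 against 3.71 and 4.96 in the other SA187 libraries.

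Adjusted over the list alone, genes that rose and fell numbered 2 and 0 (ethylene biosynthesis), 3 and 0 (salicylic acid), 2 and 0 (immunity) and 0 and 3 (clock). Counted likewise, they numbered 7 and 0 (photosynthesis), 0 and 1 (hypoxia) and 2 and 2 (ion transport). Other lists with counts above 0 were phosphate (2 and 0), oxidative stress (1 and 2), nitrogen (2 and 2), iron, jasmonate, senescence and auxin (0 and 1 each) and heat shock (0 and 3).

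Many of these calls rest on few libraries. The RD29A call was lost without salt replicate 2 (adjusted p = 0.052), salt replicate 3 (0.074) or salt with SA187 replicate 3 (0.056), and that of RAB18 in 7 alternatives, among them these 3 (0.11, 0.15 and 0.13). Calls were lost in 17 alternatives for SPX1 and GORK, 16 for CSD2 and ELF4, 12 for BT5 and NHL10, 11 for ERF2 and WRKY70, 9 for PCC1, 8 for LEA7, CAX3 and ABCG37, and 5 for ACO3 and SAG29. As deposited, without rescaling, 1190 genes passed with 275 higher and 915 lower, with quantile normalization 346 were higher and 374 lower, and with equal nuclear sums 40 and 56, so the direction split again depends on the scaling. The inoculated and non-inoculated libraries had different rRNA removal mixes, so the mix cannot be separated from SA187 in this comparison or in that without salt.

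Without salt, the comparison of SA187 with control asks what the bacterium changes in unstressed seedlings. Only 10 of 16729 genes passed, 8 higher and 2 lower, and 1707 had an unadjusted p under 0.05. DIN10 (AT5G20250), a gene induced by darkness and sugar starvation, rose from 14.9 ± 1.47 to 29.6 ± 2.87, RL5 (AT1G19510), a small MYB-like gene, rose from 1.57 ± 0.267 to 3.15 ± 0.451, and G6PD3 (AT1G24280), a plastid glucose-6-phosphate dehydrogenase gene, fell from 5.86 ± 0.2 to 3.51 ± 0.282. The other called loci were AT3G15450, AT3G21460, AT3G62950, AT3G15356, AT4G27450 and AT2G30600, higher, and AT5G41670, lower; these were named after their values were seen. AT3G15450 rose from 32 ± 2.1 to 87.5 ± 2.22. The calls of RL5, DIN10 and G6PD3 were lost in 14, 13 and 6 alternatives.

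Replicate numbers were taken to pair the libraries of this comparison, on correlations as low as 0.11 against a limit of 0.1. The fit with the replicate block, made over all 12 libraries, called 58 genes, 52 higher and 6 lower, which include all 10. In it the ethylene response factor gene ERF105 (AT5G51190) passed (adjusted p = 0.046), at 32.2 ± 8.79 with SA187 against 7.58 ± 5.39 in control. Counts without a library went from 1 (without control replicate 3) to 17 (without salt with SA187 replicate 3). They were also 2 without control replicate 2, 3 without control replicate 1, 4 without SA187 replicate 1, 5 without salt replicate 3 and 6 without SA187 replicate 2. Without SA187 replicate 2 the split was 1 higher and 5 lower, and 1 of the 10 genes was still called. With equal nuclear sums 1 gene passed, lower with SA187, and 0 of the 10.

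No member of a list passed over all genes when the block was left out. List calls with the preset correlation were not rare. Of the 10 splits of the 6 libraries compared, 3 gave as many called lists as the real 7 here, as did 4 for salt (7 lists), 4 for SA187 under salt (9) and 2 for salt with SA187 (10). The ethylene signalling list had a median of -0.04 and did not pass camera (adjusted p = 0.48). In the ethylene response list 12 of 16 genes had a positive change, with a median of 1.03, and 11 rose when adjusted over the list alone. The positive members were ERF genes, ORA59, TEM1 (AT1G25560), RAV1 and RAV2 (AT1G68840). The 4 negative members were PDF1.2, CHIB (AT3G12500), PR4 (AT3G04720) and EDF3 (AT3G25730), so the rise was not shared by the whole list. The largest change was that of ERF105, at 2.15 (SE 0.51, adjusted p = 0.16). The list was higher by camera (adjusted p = 5.2e-07; adjusted p = 0.44 with an estimated correlation). The immunity list was higher too (adjusted p = 0.0026; adjusted p = 0.44 with an estimated correlation), with WRKY40 (AT1G80840), a transcription factor gene, at 9.68 ± 4.81 against 1.32 ± 1.19. Its median of 0.16 became -0.11 with equal nuclear sums, which lowered the median of all genes to -0.27. Lower by camera was the ABA list (adjusted p = 2.9e-06; 0.54 is the adjusted p with an estimated correlation). Its score, the centred mean of the list, was -0.72, -0.06 and -0.72 in the SA187 libraries and -0.04, -0.39 and -0.14 in control, so SA187 replicate 2 lay within the control range; without it the median went from -0.28 to -0.42. Also lower were the glucosinolate list (adjusted p = 9.6e-06; adjusted p = 0.44 with an estimated correlation) and the flavonoid list (adjusted p = 0.0044; adjusted p = 0.81 with an estimated correlation). The ion transport list (adjusted p = 0.0088) and the photosynthesis list (adjusted p = 0.039) were lower as well, with adjusted p = 0.44 and 0.88 with an estimated correlation. Adjusted over the list alone, genes that rose and fell numbered 1 and 2 (ABA), 0 and 0 (glucosinolate), 0 and 0 (flavonoid), 0 and 0 (ion transport), 0 and 0 (photosynthesis) and 5 and 1 (immunity). The flavonoid list did not pass without SA187 replicate 2 (adjusted p = 0.23) or control replicate 1 (0.17), nor the ion transport list without control replicate 2 (0.07). The photosynthesis list did not pass with the clock score (0.086) or without any of control replicates 2 and 3, SA187 replicates 1 and 3 and salt replicate 1 (0.057 to 0.92). Without control replicate 2 its camera direction turned to up (median -0.02, adjusted p = 0.92). Lists gained were the clock list, lower without SA187 replicate 2 (median -0.23, adjusted p = 0.025), the iron list, higher without control replicate 1 or SA187 replicate 3 (0.00083 and 0.027), the salicylic acid list, higher without control replicate 1 (0.0069), and the root list, lower without SA187 replicate 1 (0.0064).

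The members with the largest change in these lists, none of which passed, were CYP707A3 (AT5G45340), an ABA-degrading hydroxylase gene, 6.64 ± 2.55 with SA187 against 1.61 ± 0.861, CYP79F1 (AT1G16410) 34.1 ± 2.19 against 49.7 ± 3.42, UGT79B1 4.17 ± 0.889 against 7.16 ± 2.08, HA2 (AT4G30190) 40.5 ± 3.58 against 49.1 ± 1.52, and LHCB2.2, with a log2 change of -0.75. In the other hormone and defence lists they were ACS6 (AT4G11280) 16.3 ± 4.43 against 6.58 ± 3.62 (its list had a median of -0.01 and a mean of 0.24), EIN4 (AT3G04580) 4.7 ± 0.18 against 5.23 ± 0.307, PR1 (AT2G14610) 2.59 ± 2.35 against 8.75 ± 9.28, LOX4 (AT1G72520) 2.05 ± 1.13 against 0.615 ± 0.295 and IAA1 11.1 ± 0.64 against 9.53 ± 0.787. In the nutrient and stress lists they were IRT1 38 ± 9.36 against 20.8 ± 10.9, SRG3 (AT3G02040) 3.79 ± 0.75 against 2.35 ± 0.524, NRT1.1 (AT1G12110) 31.6 ± 6.51 against 42.7 ± 3.94, LSU2 (AT5G24660) 23.3 ± 7.66 against 16.6 ± 6.7, PDC1 (AT4G33070) 1.68 ± 0.537 against 2.12 ± 0.261, GSTU25 (AT1G17180) 7.74 ± 1.74 against 11.2 ± 2.21 and HSP70 14.1 ± 1.33 against 19.2 ± 4.19. For senescence, clock, root, floral and division lists they were SEN1 (AT4G35770) 2.66 ± 0.522 against 1.21 ± 0.143, GI (AT1G22770) 4.4 ± 3.21 against 5.79 ± 2.48, BGLU21 (AT1G66270) 9.65 ± 1.23 against 6.87 ± 1.22, SOC1 5.02 ± 0.47 against 4.72 ± 0.923 and CYCB1;1 (AT4G37490) 1.03 ± 0.284 against 0.755 ± 0.154.

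The fourth comparison asks how inoculated seedlings respond to salt. By camera with a preset correlation, salt raised the flavonoid, jasmonate, phosphate and ABA lists and lowered the salicylic acid and ethylene response lists. None of these lists passed with an estimated correlation (adjusted p = 0.34 to 0.5). EARLI1 rose from 1.22 ± 0.358 to 28.7 ± 10.2, KIN1 from 6.12 ± 1.18 to 51.1 ± 10.6, and P5CS1 from 2.67 ± 0.569 to 17 ± 1.11. LURP1 fell from 21.4 ± 12.4 to 1.89 ± 0.883, and RAV1 fell from 21.9 ± 4.08 to 4.33 ± 2.13. Of 16729 genes 1779 passed, 841 higher and 938 lower, and 212 changed at least 2-fold; 1072 passed without SA187 replicate 1.

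Among genes with separate ranges and a symbol, the other large rises were those of MBP1 and LTP2, to 9.63 ± 2.39 and 33.2 ± 15.4, and the other large falls those of PCC1, to 4.61 ± 1.39, the defensin gene PDF1.3 (AT2G26010), to 0.0635 ± 0.0331 from 4.38 ± 0.711, and the small peptide gene RTFL14 (AT3G63088), to 0.875 ± 1.52 from 6.02 ± 0.493. In the ABA list 10 of 32 genes rose and 1 fell, with RD20 (AT2G33380), a caleosin gene, going from 1.32 ± 0.481 to 6.84 ± 1.17 (list adjusted p = 0.00013; adjusted p = 0.5 with an estimated correlation). In the flavonoid list 6 of 12 rose, with UGT79B1, LDOX and DFR reaching 23.2 ± 0.715, 28.7 ± 5.01 and 21.5 ± 4.07 (list adjusted p = 0.00091; adjusted p = 0.5 with an estimated correlation). In the jasmonate list 5 of 19 rose, with LOX2 going from 97.2 ± 20.6 to 282 ± 70.7, and VSP2 and CORI3 to 109 ± 12.5 and 29 ± 9.53 (list adjusted p = 1.2e-06; adjusted p = 0.5 with an estimated correlation). Salt with SA187 replicate 3 stood apart in this list, and without it the median went from 0.61 to 0.27 (adjusted p = 0.00058). In the phosphate list 5 of 9 rose, among them PHT1;1, PHT1;4 and the acid phosphatase gene PAP17 (AT3G17790), from 6.75 ± 1.52 to 12.1 ± 1.14 (list adjusted p = 0.0022; adjusted p = 0.34 with an estimated correlation). In the glucosinolate list 3 of 13 rose, MYB29 and MAM1 among them, and CYP79F2 fell to 3.81 ± 0.407 (list adjusted p = 0.019; adjusted p = 0.54 with an estimated correlation).

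In the salicylic acid list 6 of 12 genes fell, with WRKY70, NIMIN1 and WRKY54 at 13.8 ± 6.55, 1.61 ± 0.469 and 1.76 ± 0.651 (list adjusted p = 6.9e-07; adjusted p = 0.34 with an estimated correlation). In the immunity list 4 of 15 fell and 1 rose, and CYP71A12, NHL10 and FLS2 fell to 0.716 ± 0.49, 1.55 ± 0.115 and 0.907 ± 0.239 (list adjusted p = 0.0011; adjusted p = 0.34 with an estimated correlation). In the ethylene response list 5 of 16 fell and 1 rose, with ERF6 (AT4G17490) falling from 24.1 ± 5.81 to 8.25 ± 4.54 and PDF1.2 falling from 1.95 ± 0.43 to 0.0405 ± 0.0701 (list adjusted p = 0.00091; adjusted p = 0.5 with an estimated correlation). In the ethylene biosynthesis list 2 of 5 fell, ACO3 from 3.52 ± 0.949 to 1.53 ± 0.239 (list adjusted p = 0.026; adjusted p = 0.34 with an estimated correlation). The clock list was lower with no called member (adjusted p = 0.016; adjusted p = 0.5 with an estimated correlation), and did not pass without SA187 replicate 2 (adjusted p = 0.15).

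In the ion transport list HKT1 rose from 0.703 ± 0.0404 to 1.59 ± 0.108 and NHX2 (AT3G05030), a vacuolar exchanger gene, to 2.09 ± 0.0434, while CAX1 fell to 9.12 ± 3.35. NRT2.1 and ASN1 rose to 15.2 ± 3.87 and 3.13 ± 0.473, and NIA1 fell to 42.3 ± 5.17. SUS1 rose to 4.13 ± 0.353, and F6'H1, SEN1 and SOC1 fell to 15.8 ± 0.59, 0.794 ± 0.168 and 2.88 ± 0.254. No member passed in the ethylene signalling, photosynthesis, sulfur, auxin, oxidative stress, heat shock, clock, root or cell division lists. The members with the largest change stood in salt with SA187 at: EBF2 (AT5G25350) 2.06 ± 0.325, LHCB2.2 49.9 ± 25.2, IAA2 35.9 ± 5.96, CSD1 (AT1G08830) 3.86 ± 0.0394, HSP70 12.4 ± 2.32, GI 2.61 ± 1.88, CASP1 13.8 ± 1.24 and KN (AT1G08560) 13.2 ± 2.26, and LSU1 had a log2 change of 0.49. Adjusted over the list alone, genes that rose and fell numbered 11 and 1 (ABA), 6 and 2 (flavonoid), 9 and 0 (jasmonate), 6 and 0 (phosphate), 4 and 1 (glucosinolate) and 0 and 8 (salicylic acid). Counted likewise, they numbered 1 and 5 (immunity), 1 and 9 (ethylene response), 0 and 2 (ethylene biosynthesis), 0 and 0 (clock) and 3 and 1 (ion transport). With the clock score as covariate the glucosinolate and flavonoid lists did not pass (adjusted p = 0.083 and 0.092), and with equal nuclear sums 364 genes passed. The ethylene biosynthesis list did not pass without SA187 replicate 1 (0.06) or salt with SA187 replicate 2 (0.062), the glucosinolate list without SA187 replicate 3 (0.14), or the clock list without salt with SA187 replicate 3 (0.054). Lists gained were photosynthesis, higher with the clock score (median 0.24, adjusted p = 1.3e-05) and without SA187 replicate 2 (median 0.24, adjusted p = 0.0052) against a median of 0.06 otherwise, and root, lower without SA187 replicate 3 (0.018) or salt with SA187 replicate 1 (0.0071). Calls were lost in 10 alternatives for MAM1 and MYB29, 8 for NIA1 and PHT1;1, 6 for CYP79F2 and F6'H1, and 5 for WRKY70.

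**Figure D3:**
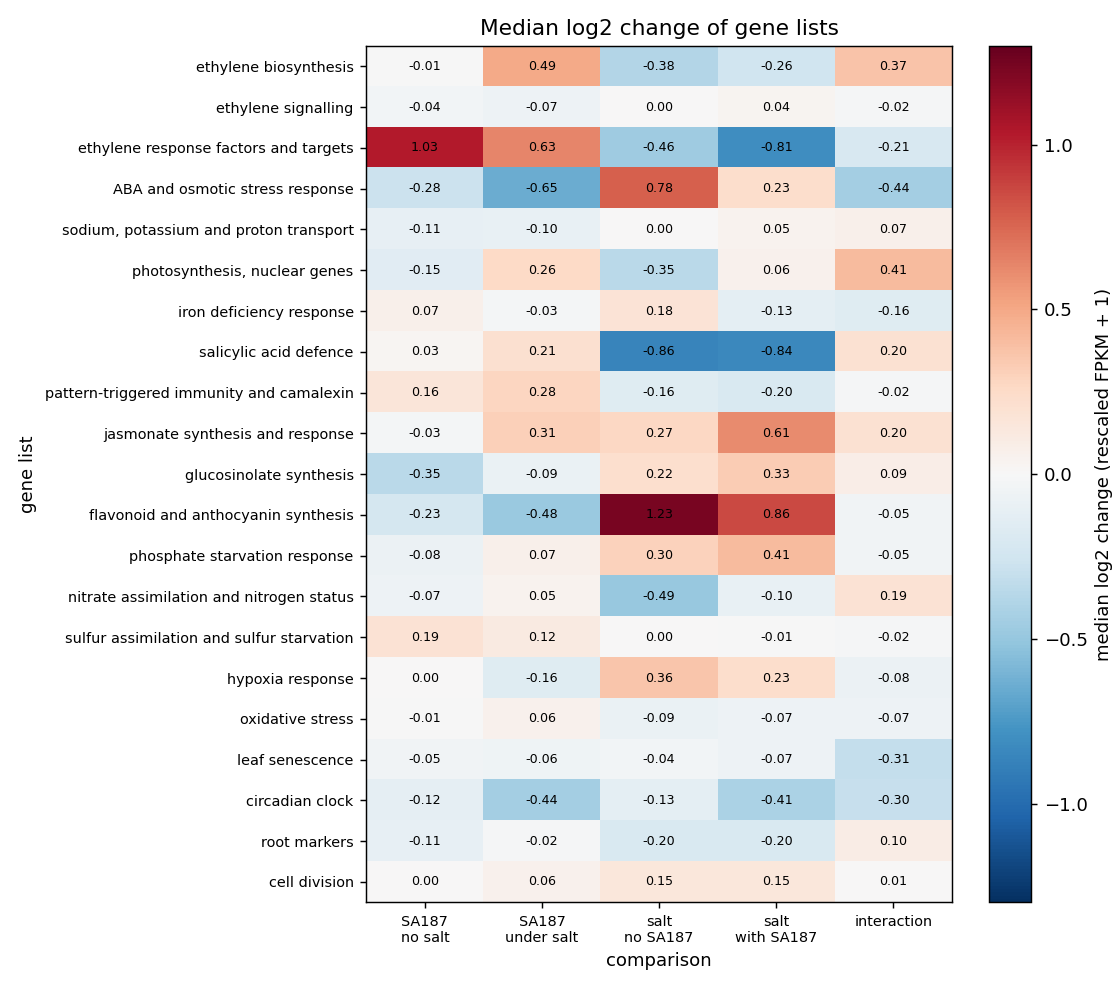
Median log2 change (colour and printed value) of 21 fixed gene lists (rows) in the 4 comparisons and the interaction (columns). The ABA and osmotic stress list has medians of 0.78 for salt without SA187 and -0.65 for SA187 under salt.

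Whether the salt response differs between inoculated and non-inoculated seedlings was tested by the interaction of salt and SA187. HKT1, ASN1 and 19 other genes passed, 7 with a positive and 14 with a negative interaction. HKT1, which retrieves sodium from the xylem, went from 0.785 ± 0.0271 to 0.546 ± 0.0629 with salt alone and from 0.703 ± 0.0404 to 1.59 ± 0.108 in inoculated seedlings, an interaction of 0.81 (SE 0.08, adjusted p = 0.0024). ASN1 went from 1.04 ± 0.127 to 9.16 ± 1.41 and from 1.71 ± 0.508 to 3.13 ± 0.473, an interaction of -1.69 (SE 0.19, adjusted p = 0.0053). XTH7 (AT4G37800), a cell wall enzyme gene, FRO4 (AT5G23980), a ferric reductase gene, and CYP712A1 (AT2G42250) had interactions of 1.09, 0.99 and 0.97, and HAI2, MGL (AT1G64660), a methionine-degrading enzyme gene, NUDT24 (AT5G19470) and GPT2 (AT1G61800), a plastid glucose phosphate transporter gene, of -1.31, -1.28, -1.14 and -1.04. The count ranged from 2 without salt replicate 2 to 26 without salt with SA187 replicate 2, and was 10 with the replicate block, 9 of them among the 21. As deposited 5 were positive and 20 negative, and with equal nuclear sums 6 and 5. HKT1 kept its call in each alternative that tested it. It was not tested with the stricter filter or without any one of the salt with SA187 libraries, where it fell below the filter; it stood at 1.55, 1.71 and 1.5 in those libraries and at 0.478, 0.559 and 0.602 in salt. HAI2 and MGL lost their calls in 17 and 16 alternatives, XTH7, CYP712A1 and GPT2 in 9, FRO4 in 6, and ASN1 and NUDT24 in 1. Other counts were 3 without salt replicate 3, 6 each without control replicate 2, control replicate 3 and salt with SA187 replicate 3, 7 without salt replicate 1, and 10 without salt with SA187 replicate 1.

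Of the lists, ABA and osmotic stress had a negative interaction (median -0.44, 28 of 32 genes negative, adjusted p = 9e-11; adjusted p = 0.88 with an estimated correlation). The photosynthesis list had a positive one (median 0.41, 29 of 34 genes positive, adjusted p = 2.4e-05; adjusted p = 0.88 with an estimated correlation). Its median was 0.27 as deposited, 0.20 with quantile normalization and 0.89 with equal nuclear sums. With the clock score as covariate the ethylene response list (median -0.45, adjusted p = 0.0035) and the flavonoid list (median -0.27, adjusted p = 0.00018) passed as well; without it their medians were -0.21 and -0.05, and 0.25 and 0.36 with equal nuclear sums. That scaling raised the median interaction of all genes to 0.39. The ABA and photosynthesis lists passed without each library, and 2 to 5 lists passed in all. Negative lists gained were iron without control replicate 1, SA187 replicate 3 or salt with SA187 replicate 2 (adjusted p = 0.0013, 0.013 and 0.0059), flavonoid without control replicate 1 (0.031), senescence without SA187 replicates 1 or 3 or salt with SA187 replicate 3 (0.047, 0.03 and 0.044), and clock without SA187 replicate 1 (0.039). Negative too were hypoxia without SA187 replicate 3 or salt with SA187 replicate 3 (0.023 and 0.044) and ethylene response without the latter (median -0.48, adjusted p = 0.026). Positive lists gained were salicylic acid without control replicate 2 (0.0042), glucosinolate without salt replicate 1 (0.00084) and jasmonate without salt with SA187 replicate 2 (0.013). Counts of called lists did not exceed chance here, since 95 of 100 draws with permuted residuals gave 2 or more.

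Across genes, which are not independent replicates, the salt effects without and with SA187 had a Pearson r of 0.738 and a Spearman rho of 0.627. Of the calls, 613 rose and 815 fell in both, where independent lists would share 93.1 and 145. The SA187 effects without and under salt had r = 0.322 and rho = 0.229. They shared 5 rises and 1 fall, against 0.223 and 0.0363. The salt effect and the SA187 effect under salt, which share the salt libraries, had r = -0.677 and rho = -0.639, where unchanged groups simulated with the same spread gave -0.491 and -0.463. Their covariance was -0.0794 against a simulated -0.0136, a difference of -0.0658. Of the 770 SA187 calls under salt, 635 (82.5%) were genes called by salt in the opposite direction and 6 in the same; independent lists would share 33.6 and 71.8 opposite calls for salt rises and falls, where 261 and 374 were found. Independent lists take no account of the shared salt libraries. In 100 simulations chosen after seeing the data, with those libraries shared and the direction of the SA187 effect random for each gene, on average 57.3% (at most 62.1%) of the calls in both comparisons were opposite, against 99.1% of 641 here. These simulations drew noise separately for each gene, so they hold no deviation of a library that many genes share. The 3 salt libraries cannot be divided so that each part keeps at least 2, so a contribution from sharing them is not ruled out. A Deming line of the salt change with SA187 on that without had a slope of 0.638 over all genes, 0.593 to 0.717 without each library. Over the 32 genes of the ABA list the slope was 1.01, 0.944 to 1.08 without each library, with an offset of -0.54 (-0.32 without SA187 replicate 2) against 0.02 over all genes.

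**Figure D4:**
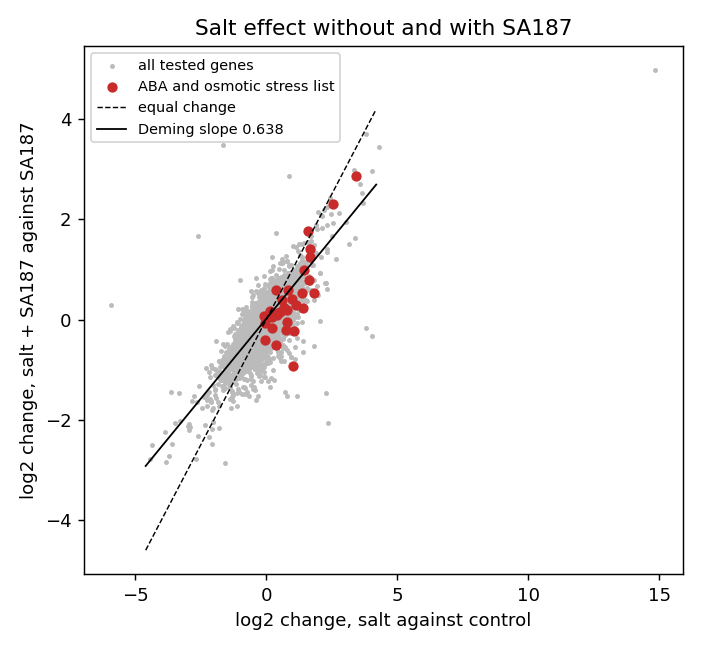
Log2 change of each tested gene by salt without SA187 (x axis) and with SA187 (y axis); grey points are all tested genes, red points the ABA and osmotic stress list, the dashed line equal change and the solid line the Deming slope of 0.638. A single gene listed at 0 in every control library lies at 14.85 on the x axis.

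In the bacterium, salt with SA187 was compared with SA187 over 811 bacterial genes. 4 passed, all lower with salt, and 97 had an unadjusted p under 0.05. The files give no gene names for these identifiers. SA187PBcda_000000655 stood at 31.1 ± 12.1 without salt and was listed at 0 in all 3 libraries with salt (adjusted p = 0.0037), and SA187PBcda_000003585 fell from 13.9 ± 6.22 to 0.65 ± 0.189 (adjusted p = 0.018). None passed with the replicate block or without SA187 replicate 2. Without one of SA187 replicate 1, SA187 replicate 3 and salt with SA187 replicate 1, 1 passed, and 11 passed without salt with SA187 replicate 2.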

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

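The tests on explanations in this part, and the draws within replicate numbers, were chosen after the results were seen, while those on other splits of the libraries and on residuals permuted over all libraries were not.

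The response to salt differed between inoculated and non-inoculated seedlings, by the interaction test, in 21 genes. The named ones had interactions of 1.09 (XTH7), 0.99 (FRO4), 0.97 (CYP712A1), 0.81 (HKT1), -1.69 (ASN1), -1.31 (HAI2), -1.28 (MGL), -1.14 (NUDT24) and -1.04 (GPT2). When residuals of the fit without interaction were permuted, 1 of 100 draws, the real one, gave 21 or more genes, and the highest other gave 1, which excludes chance for the count if libraries are exchangeable. Same-numbered libraries are not fully so: with the replicate block 10 genes passed (9 of the 21), and 4 of 100 draws with residuals permuted within replicate numbers gave 10 or more. Counting the real one, that share lies just under 0.05, but the highest other draw gave 1082. Such draws can thus give far more genes than the real libraries, so chance is not firmly excluded for the count with the block. What produced that draw was not tested. By camera with a preset correlation the ABA and osmotic stress list had a median interaction of -0.44 and the photosynthesis list one of 0.41, but neither passed with an estimated correlation (adjusted p = 0.88 for both). The photosynthesis median was 0.20 with quantile normalization and 0.89 with equal nuclear sums. The count of interaction lists does not exceed chance: 95 of 100 draws gave 2 or more, up to 12. For the list medians themselves, 1 of 100 draws, the real one, was as far from 0 as that of the ABA list (highest other 0.42), and 7 of 100 for the photosynthesis list (highest other 0.63), so chance is not excluded for the latter. Within replicate numbers 2 of 100 draws were as far from 0 as the ABA list (highest other 0.44).

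The negative interaction of the ABA list, median -0.44, was weighed against 3 technical explanations. These tests concern only the difference from the change without salt (median -0.28), not the whole change of -0.65 under salt. With 0 pairs of libraries on one mix with and without SA187, the mix and SA187 cannot be told apart for the part of that change also seen without salt. For the interaction, an rRNA removal mix adding the same log2 change with and without salt would leave no interaction. The median interaction stayed below 0 without each library, at most -0.27 (without SA187 replicate 2, jackknife SE 0.19). A mix acting by the same fold would still give a smaller log2(rescaled FPKM + 1) change in genes that are low without salt. GolS2 (AT1G56600), for example, stood at 1.76, 2.25 and 2.17 in control and 9.69, 8.06 and 8.39 in salt. The list median was not computed with a smaller pseudocount, so this test does not decide on the mix. The median of -0.02 with equal nuclear sums does not decide on rescaling, and that scaling raised the median interaction of all genes to 0.39. Relative to all genes the highest value over the 3 other scalings was -0.40, so the list stood below the bulk of genes under each. A factor per library moves all genes nearly alike, so this relative value could hardly differ between scalings. Rescaling thus stays undecided for the interaction of -0.44 itself. A weaker salt response of all genes, with a slope of 0.638, left a median remainder of -0.19 in the list (jackknife SE 0.17). Without each library the remainder ran from -0.29 to -0.06, the latter without SA187 replicate 2. The list's own slope was 1.01, with an offset of -0.54. A remainder hardly larger than its SE does not decide on that explanation. With the clock score as covariate the medians were -0.54 under salt and -0.41 for the interaction, and a biological effect of SA187 on the salt response of the ABA list may remain, as a hypothesis.

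The higher ethylene response list with SA187 without salt, median 1.03, was weighed against harvest time, scaling and the rRNA mix. With the clock score as covariate the median was 0.88 (jackknife SE 0.33), and lowest at 0.58 without SA187 replicate 2. That stayed above 0.5 of the value without the covariate, the limit set for clock phase. The score is a plain mean of the clock list, however, and its group means were 0.16 in control and 0.05 with SA187. A covariate that differs so little between the groups can remove little of the change, so harvest time stays undecided. The median of 0.74 with equal nuclear sums does not decide on rescaling, and that scaling took the median of all genes to -0.27. Relative to all genes the lowest median over the 3 other scalings was 1.01 (jackknife SE of the median 0.29). The list thus stood above the bulk of genes under each scaling. A factor per library moves all genes nearly alike, so this relative value could hardly differ between scalings. It does not decide on rescaling for the change itself. There are 0 pairs of libraries on one mix with and without SA187, so the mix and SA187 cannot be told apart here. The 10 splits of the 6 libraries are too few for a share under 0.05; the real median was the farthest from 0 in 1 of 10, and the highest other was 0.75.

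For counts of genes the 10 splits of 6 libraries are likewise too few. The real split gave the most genes, in 1 of 10, for SA187 without salt (10, highest other 2), salt without SA187 (4430, highest other 0), SA187 under salt (770, highest other 483) and salt with SA187 (1779, highest other 1). With the control and SA187 libraries taken as pairs, the 3 other splits that part all 3 pairs gave 0, 2 and 0 genes. The split with 483 genes set salt replicate 1 and salt with SA187 replicates 1 and 3 against the others; these had the lowest clock scores of the 6, which points to a structure of the samples other than the groups. For counts of called lists 3, 4, 4 and 2 of 10 splits gave as many as the real 7, 7, 9 and 10, with highest others of 12, 10, 11 and 10. For bacterial genes 3 of 10 splits gave 4 or more, the highest other 5.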

How the results depend on the processing

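The clock covariate, the bacterial alternatives, the lists without each library and the correlations without 2 genes of extreme change were chosen after seeing the data; the cause of a change was not tested unless given. Of 180 named results 132 passed with the settings described above. None of these 132 changed direction in any alternative that tested them, and 63 of them lost their call in at least 1. Changes of direction were not counted for the named results that did not pass. SOC1 for SA187 without salt, for example, went from 0.08 to -0.21 with equal nuclear sums. Genes below the filter of an alternative have no value there: many with the stricter filter, HKT1 without each salt with SA187 library, GPT2 and NUDT24 without each salt library, and SAG29 without control replicate 1, salt replicate 2 or salt replicate 3.

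For SA187 without salt (10 genes) the count was 6 with the stricter filter, 19 as deposited, 1 with equal nuclear sums, 835 with array weights, 58 with the replicate block and 83 with the clock covariate, and 1 to 17 without each library. For salt without SA187 (4430) it was 2091 with the stricter filter, where fewer genes are tested, 2169 with equal nuclear sums and 10632 with array weights, and 2729 to 4573 without each library. For SA187 under salt (770) it was 1190 as deposited, 96 with equal nuclear sums, 3381 with array weights, 465 with the clock covariate and 221 with only the libraries compared, and 122 to 1231 without each library. For salt with SA187 (1779) it was 735 with the stricter filter, 364 with equal nuclear sums and 1140 with only the libraries compared, and 1072 to 1922 without each library. For the interaction (21) it was 12 and 13 with pseudocounts of 0.1 and 0.5, 11 with no filter, 4 with the stricter filter, 11 with equal nuclear sums, 978 with array weights, 10 with the replicate block and 46 with the clock covariate, and 2 to 26 without each library. Array weights ran from 0.332 to 6.67, so a few libraries carried most of those fits. AT2G01021 made up 16.9% to 56% of the nuclear sum, so that scaling follows one locus. As deposited, the median change of all genes moved to 0.13 for salt and -0.11 for SA187 under salt.

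The correlation of the SA187 effects (0.322) was 0.215 with equal nuclear sums; the other correlations moved by less than their jackknife spread in the alternatives run. With an estimated correlation 0 lists passed in each of the 5 tests. Without each library 5 to 8, 5 to 8, 5 to 11 and 9 to 11 lists passed in the comparisons, in the order above, and 2 to 5 for the interaction. For salt without SA187 4 of 7 lists passed with quantile normalization. With the clock covariate 3 of 9 passed for SA187 under salt and 4, against 2, for the interaction. The clock list was among those lost under salt, a loss that is built in because the score is the mean of that list. The bacterial count (4) was 0 with the replicate block and 0 to 11 without each library.

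Same-numbered libraries correlated over 0.1 in all 3 pairs only for control and SA187, where the replicate block changed no list call. The correlations were 0.05, -0.06 and -0.01 for control and salt, 0.14, 0.39 and 0.01 for salt and salt with SA187, and 0.2, 0.31 and 0 for SA187 and salt with SA187; with the block these comparisons gave 4877, 949 and 2037 genes. Depth differed less than 2-fold between libraries, and unknown totals limit what can be said of genes near 0.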

Other observations

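The test of the gene set below was fixed before its result was seen, on genes other than those that prompted it.

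Genes induced when carbon is scarce formed a group not described above. DIN10, whose call was lost in 13 alternatives, and AT3G15450, both higher with SA187 without salt, prompted the hypothesis that inoculated seedlings show a low-carbon response. Of 9 other genes known to be induced by low sugar or the energy-sensing kinase SnRK1, 8 were measured, and all 8 had a positive change with SA187 without salt. TPS8, a class II trehalose phosphate synthase gene, stood at 4.1 ± 0.409 in control and 7.08 ± 0.302 with SA187 (mean ± SD of 3 libraries), TPS11 at 3.28 ± 0.0956 and 5.27 ± 0.867, AKINBETA1, a subunit gene of that kinase, at 2.2 ± 0.139 and 3.29 ± 0.205, and BT2 at 68.6 ± 3.53 and 106 ± 13.1. The median log2 change was 0.45, and 0.43 with the clock score as covariate. Camera gave p = 7.3e-07 with the preset correlation, p = 7.6e-07 with the clock score and p = 0.017 with an estimated correlation, while 0 of the 8 passed over all genes with limma. In 1 of 10 splits, the real one, the median was this far from 0 (highest other 0.19), too few splits to exclude chance. For SA187 under salt the median of these genes was 0.39, with DRM2 (AT2G33830) at -0.19, TPS10 (AT1G60140) at -0.16 and the others positive. The set was read in the same libraries as the genes that prompted it, so it is not independent of them. A low-carbon response is thus a hypothesis that these values may support, and the rRNA removal mix and the hour of harvest remain open for it. The clock score had group means of 0.16 in control and 0.05 with SA187. As a covariate it can remove little of a change between them, so the fit with it does not decide on harvest time.

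Clock genes varied between libraries of one group. GI stood at 3.24, 8.19 and 5.94 in control, 2.38, 8.11 and 2.72 with SA187, 3.1, 6.03 and 8 in salt, and 1.58, 4.78 and 1.47 in salt with SA187. PRR7 stood at 0.477, 1.45 and 0.537 in the SA187 libraries and at 0.305, 0.942 and 0.316 in the salt with SA187 libraries. The labels used here give no hour of harvest.

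AT5G64395 was listed at 0 in the control and SA187 libraries and at 39100, 25500 and 34800 FPKM in the salt libraries, and at 31700, 0 and 0 in salt with SA187. The plastid gene ATCG00590 ranged from 0 to 119000 FPKM within the 12 libraries. In salt replicate 1, salt replicate 2 and salt with SA187 replicate 1 ATCG00590 stood at 39100, 102000 and 63400. These are near whole multiples of the AT5G64395 values there. Such steps leave open that both genes rest on very few fragments, whose number is not known. Without these 2 genes the Deming slope of the salt effects was 0.669.

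Of the 4120 bacterial genes, 242 were above 0 in at least 1 non-inoculated library. For 33 the mean of the non-inoculated libraries was over 0.1 of that of the inoculated ones. Summed bacterial FPKM in salt replicate 3 was 227800, against 5461 to 9856 in the other non-inoculated libraries.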
